A study of Mus musculus with 2 samples.

How the data were processed

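The study deposited single-cell RNA counts of ILC3s sorted from the small-intestinal lamina propria of aged mice, made on the BD Rhapsody system with sample tags. Per the file headers, the deposited counts were made by the authors with the BD WTA Multiplex Rhapsody Analysis Pipeline 1.8 against GRCm38 with PhiX and GENCODE M19, and are unnormalised UMI counts per cell and gene, corrected by recursive substitution error correction. The submitters' notes also name mm10, GRCm38.p6, HISAT2 2.0.5 and Bowtie2. A second deposited file per library gives the pipeline's sample tag call for each cell.

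Each replicate was 1 tag of its own library, tag 6 in replicate 1 and tag 12 in replicate 2, and each library was a separate pipeline run. Library 1 held 15793 cells and 22671 genes, of which 3427 cells carried the replicate's own tag. Library 2 held 16531 cells and 20039 genes, with 3954 cells of its own tag. Cells of the 3 other tags in each library (10666 and 10916), multiplets (572 and 987, or 3.62% and 5.97%) and undetermined cells (1128 and 674) were not used in any step. Counts of the own tag came to 7011649 and 6845914 UMIs. The tables shared 19031 genes, and a gene absent from 1 table was read as 0 there. Gene positions came from GENCODE M21 on GRCm38, a later release than the pipeline's, matched by symbol.

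Cells with at least 300 genes and at most 25% mitochondrial counts were kept, 97.4% and 97.1% of the cells with the own tag, and 90 and 114 were left out. For clustering with scanpy 1.11.5, counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were picked within the samples without the genes of the test lists, mitochondrial genes and ribosomal protein genes. Each gene was centred within each sample, and 20 principal components (scikit-learn 1.9.0), 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 0.6 gave 6 clusters. No doublet caller was used beyond the tag multiplets. Scrublet was tried as an alternative and marked 1 cell per sample (0.030% and 0.026%), so it has not worked on these data.

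Clusters were named from 13 marker lists by the mean log2 ratio of CPM with a prior of 10 CPM. A cluster entered the ILC3 classes if its highest list was an ILC3, LTi, NCR or T cell list and its ILC3 score exceeded -0.3, and it was then named for the highest of the LTi, NCR and T cell scores. The marker lists were fixed before the data were examined, but the thresholds of this rule were set after seeing the clusters. It left 1 of the 6 clusters, with 9.90% of the cells, outside every class. Cluster 1 and cluster 2 were NCR-like. Cluster 1 (39.6% and 45.4% of cells) was led by Nos2, Gjb2 and Ncr1 and by the light chain genes Iglc3 and Iglc2, whose UMIs came almost all from single cells. Cluster 2 (10.9% and 10.2%) was led by the heat shock genes Hspa1b and Hspa1a with Tff2 and Gkn3. The T-like cluster was led by Blk, Ccr2, Cd40lg and Trdc, the LTi-like by Vegfa, Cacna1g and Cd83, the unnamed by Ccl5, Il21r and Gzma, and the stromal-like by Col1a1 and Adamdec1. Genes used for clustering define the classes and are not given as results.

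Counts were summed per sample and class, and classes with at least 20 cells in each sample entered the fit. Class sums held 3426443 and 3841473 UMIs for NCR-like, 594534 and 346372 for LTi-like and 1527566 and 1863335 for T-like cells in replicates 1 and 2. The sums were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM scaling, filterByExpr and the sample as a block, and with p-values adjusted by Benjamini-Hochberg at 0.05 over the 7683 tested genes not used for clustering. The fit had 2 residual degrees of freedom per gene and a common dispersion of 0.00651. The classes were clusters of these same cells, so genes that vary with the clustering genes are parted by the clustering itself. Leaving out the clustering genes does not remove this. The p-values between classes are therefore no independent test of a difference and may be too small. Log2 ratios over both samples are edgeR's estimates. Their standard errors were derived from each ratio and its F statistic. Log2 ratios of single replicates are differences of log2 CPM with TMM scaling and a prior count of 2. This prior pulls ratios on few counts toward 0, so they are not the same measure as edgeR's estimates. The 95% intervals of log2 ratios use a normal distribution and may be too narrow for so few degrees of freedom. Levels in CPM are UMIs per class sum without TMM scaling.

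For 18 gene lists with 291 genes (288 found), fixed before the data were examined, camera (limma 3.58.1) tested each list against the other genes with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. Fry tests whether a list's genes move on balance one way and compares them with no other genes. Counts of genes past 0.05 are given over all genes tested and adjusted over the list alone.

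Named genes followed a rule fixed before the data were examined. Cxxc1, Klf4, Il22, Il17a, Il17f, Csf2, Ifng and Il23r are always given, and 1 other gene of that rule is not reported here. From each list up to 3 genes with the largest ratio past the threshold, the same direction in both samples and at least 10 CPM are added, 25 at most. For NCR-like against LTi-like cells, up to 5 genes higher and 5 lower outside the lists are added, and between samples the 5 genes highest in each. Members of lists named beside them, and all genes of the unnamed class, were chosen after their values were seen.

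Shares carry exact Clopper-Pearson and single levels exact Poisson 95% intervals (scipy 1.17.1). Folds against a class without counts are bounds against a floor of 3 counts, and folds against 1 to 3 counts carry a counting interval. Shares of cells with a UMI were taken after thinning each cell to 1300 UMIs, the 25th percentile rounded down, which 5739 cells reached and 1438 did not. The samples were compared by correlation across genes of log2(CPM + 1).

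The alternatives were a looser cell filter (200 genes, 40% mitochondrial counts) and a stricter one (500 genes, 15%), Leiden resolutions 0.3 and 1.0, 1000 variable genes, no centring, removal of Scrublet calls, DESeq2's size factors, DESeq2 1.42.0 in place of edgeR, no filter on low counts, no sample block, only the compared classes in the fit, classes from UMIs of Ccr6, Cd4 and Ncr1, thinned cells, and each replicate left out. Added after seeing the data were UMI classes within the NCR-like and LTi-like clusters, and fits without the cluster led by heat shock genes, without cells with a Cd3d, Cd3e, Cd3g or Trac UMI, and without cells with a B, plasma or myeloid marker UMI (Igkc, Jchain and Cst3 not counted).

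The test was tested on simulated data, in which some genes were shifted in the summed counts. It recovered 17 of 64 genes shifted 1.5-fold, 35 of 65 shifted 2-fold and 54 of 62 shifted 4-fold, and 6 of its 112 calls were false. Camera with the preset correlation found the shifted list (adjusted p = 1.26e-106) and called 0 of the 17 other lists. Camera with an estimated correlation missed the shifted list (adjusted p = 0.0679) and fry found it (adjusted p = 0.0423). The simulated genes were drawn independently of one another, so this does not show which correlation suits lists whose genes move together. Classes were fixed in the simulation, so it does not cover errors from the clustering. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Cells of other tags, whose identity the labels do not give, were not analysed here.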

Results

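Single-cell RNA sequencing measured transcripts of group 3 innate lymphoid cells (ILC3s), lymphocytes without antigen receptors that secrete IL-22 and IL-17 in the gut wall, sorted from the small-intestinal lamina propria of 18-month-old male C57BL/6 mice. The data form 1 group of n = 2 replicates. The labels state neither a genotype nor whether the replicates were separate animals. Each SD measures only the spread between these 2 samples. P-values of the main fit measure only how evenly class ratios held in these 2 samples, with the difference between the samples taken out as a block. Both kinds of spread may be technical. As the classes were clusters of the same cells, these p-values are no independent test that the classes differ. Replicate 1 gave 3337 cells with 6939790 UMIs in all and a median of 1880.0 UMIs and 998 genes per cell. Replicate 2 gave 3840 cells with 6810214 UMIs and a median of 1674 UMIs and 889 genes. With 1 group in the labels used here, young or Cxxc1-deficient cells were not analysed, so the questions are which kinds of cell the sort held and how they differed in effector genes and in Cxxc1, the chromatin factor the series is about. Cxxc1 encodes the CpG-binding subunit of the SETD1 complexes that methylate histone H3 on lysine 4.

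The cells fell into 5 classes. NCR-like cells, named for the natural cytotoxicity receptor gene Ncr1, were the largest class at 53.1% ± 3.59 of kept cells (SD, n = 2). Their 2 clusters had NCR scores of only 0.06 and 0.01 and took the name because their LTi and T cell scores were lower still. A Ncr1 UMI was found in 33.4% and 18.5% of NCR-like cells in replicates 1 and 2. It was found in 3.20% and 5.02% of LTi-like, 0.903% and 0.550% of T-like and 14.8% and 13.9% of unnamed cells. T-like cells, in which T cell receptor complex genes stood beside part of the ILC3 markers, made up 25.8% ± 3.65. LTi-like cells, named for the lymphoid tissue inducer markers Ccr6 and Cd4, made up 8.73% ± 3.55. The T-like cluster's ILC3 score was only 0.06. A Cd3e UMI was found in 80.8% and 56.9% of T-like cells. The ILC3 marker Kit was found in 8.39% and 7.52% of them, against 48.8% and 37.5% of NCR-like cells. Il7r, another such marker, was found in 95.1% and 93.9% against 92.9% and 93.8%. T-like cells may be T cells, and only the naming rule counts them among the ILC3 classes. A cluster that no marker rule named held 9.90% ± 1.51, and stromal-like cells with collagen transcripts held 2.5% ± 2.18. The stromal-like cluster also scored high for B or plasma cell (1.19) and myeloid markers (1.34) beside stromal markers (1.5), so it was not purely stromal, and its share was 1.42% and 1.46% with the looser and stricter cell filters, 1.47% at Leiden resolution 1.0 and 1.59% with 1000 variable genes.

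LTi-like cells were 11.2% of replicate 1 (exact Clopper-Pearson 95% interval 10.2 to 12.4) and 6.22% of replicate 2 (5.48 to 7.03), and stromal-like cells were 4.05% (3.40 to 4.77) and 0.964% (0.679 to 1.33). NCR-like shares were 50.5% (48.8 to 52.2) and 55.6% (54.0 to 57.2), and T-like shares were 23.2% (21.8 to 24.7) and 28.4% (27.0 to 29.8). These intervals cover counting error only, and they describe sorted and captured cells rather than the tissue. Median UMIs per cell differed by class, with 1899.5 and 1705 in NCR-like cells of replicates 1 and 2 against 1461 and 1363 in LTi-like cells. With 1000 in place of 2000 variable genes the NCR-like share was 33.8%, the LTi-like share 15.4% and the unnamed share 22.2%, so the borders between classes were not sharp.

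**Figure D1:**
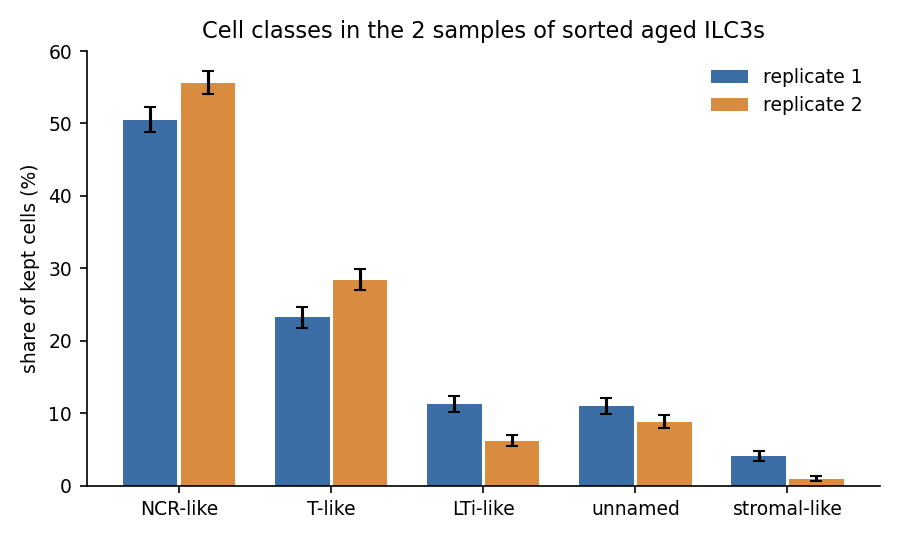
Share of kept cells (percent, vertical axis) in each cell class (horizontal axis) for replicates 1 and 2, with exact Clopper-Pearson 95% intervals. NCR-like cells were the largest class in both replicates, at 50.5% and 55.6%, and the LTi-like share was 11.2% and 6.22%.

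The first comparison asked how the NCR-like and LTi-like subsets differed in the genes that carry out ILC3 functions. LTi-like cells had more Il22, Il17f and Vegfa transcripts. Il22, whose product drives epithelial defence, stood at 3904 ± 102 CPM (UMIs scaled to the same total in each class sum, mean ± SD, n = 2) in LTi-like and 2576 ± 162 in NCR-like cells. It was 1.51-fold higher in LTi-like cells (log2 ratio NCR-like over LTi-like -0.59 ± 0.07 SE, adjusted p = 3.7e-06). Il17f, a neutrophil-recruiting cytokine, was 4.65-fold higher in LTi-like cells, at 218 ± 10.3 against 46.5 ± 4.22 CPM (adjusted p = 2.4e-08). Vegfa, the vascular growth factor, was 20.8-fold higher there, at 563 ± 156 against 26.5 ± 0.777 CPM (adjusted p = 5.4e-13). Csf2, which encodes the myeloid growth factor GM-CSF, went the other way and was 1.56-fold higher in NCR-like cells (log2 ratio 0.64 ± 0.16, adjusted p = 0.010). Il17a had a log2 ratio of -0.96 ± 0.35 and did not pass (adjusted p = 0.082). It passed when each cell was thinned to equal depth (-1.57), with a looser cell filter (-1.48) and without cells carrying Cd3 or Trac UMIs (-1.25). It also passed with classes taken from Ccr6, Cd4 and Ncr1 UMIs (-2.79). In that setting 125 of 259 and 92 of 161 LTi-like cells of replicates 1 and 2 lay outside the NCR-like and LTi-like clusters. T-like cells had the most Il17a, but a Cd4 UMI was found in only 2.84% and 1.19% of them. Among unnamed cells it was found in 26.2% and 20.9%. An Il17a UMI was found in 2.19% and 2.36% of unnamed cells, against 2.4% and 3.77% of cells in the LTi-like cluster. How far the outside cells moved the Il17a ratio was not tested. Of the 11 cytokine genes tested, 2 were higher in NCR-like cells, Csf2 and Areg, and 4 were higher in LTi-like cells, Vegfa, Il17f, Lif and Il22, or 3 and 5 adjusted over the list alone. The list's camera test gave a lower level in NCR-like cells (adjusted p = 1.6e-07, and adjusted p = 0.19 with an estimated correlation). Its mean log2 ratio was -0.52 and its median 0.01. The Il22 call ended with 1000 variable genes (-0.20) and without the sample block. The Csf2 call ended with DESeq2, without the block, with the stricter cell filter (0.10), at Leiden resolution 0.3 (0.40), with 1000 variable genes (0.23), with Scrublet calls removed (0.33) and with classes from UMIs within the clusters (0.47).

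On GRCm38 with GENCODE M21, Il22 lies on chromosome 10 at 118204942 to 118210047, Il17a on chromosome 1 at 20730905 to 20734496 and Vegfa on chromosome 17 at 46016993 to 46032369. H2-Aa lies on chromosome 17 at 34282744 to 34287823, Ccr9 on chromosome 9 at 123678439 to 123784330 and Vipr2 on chromosome 12 at 116077726 to 116146261.

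**Figure D2:**
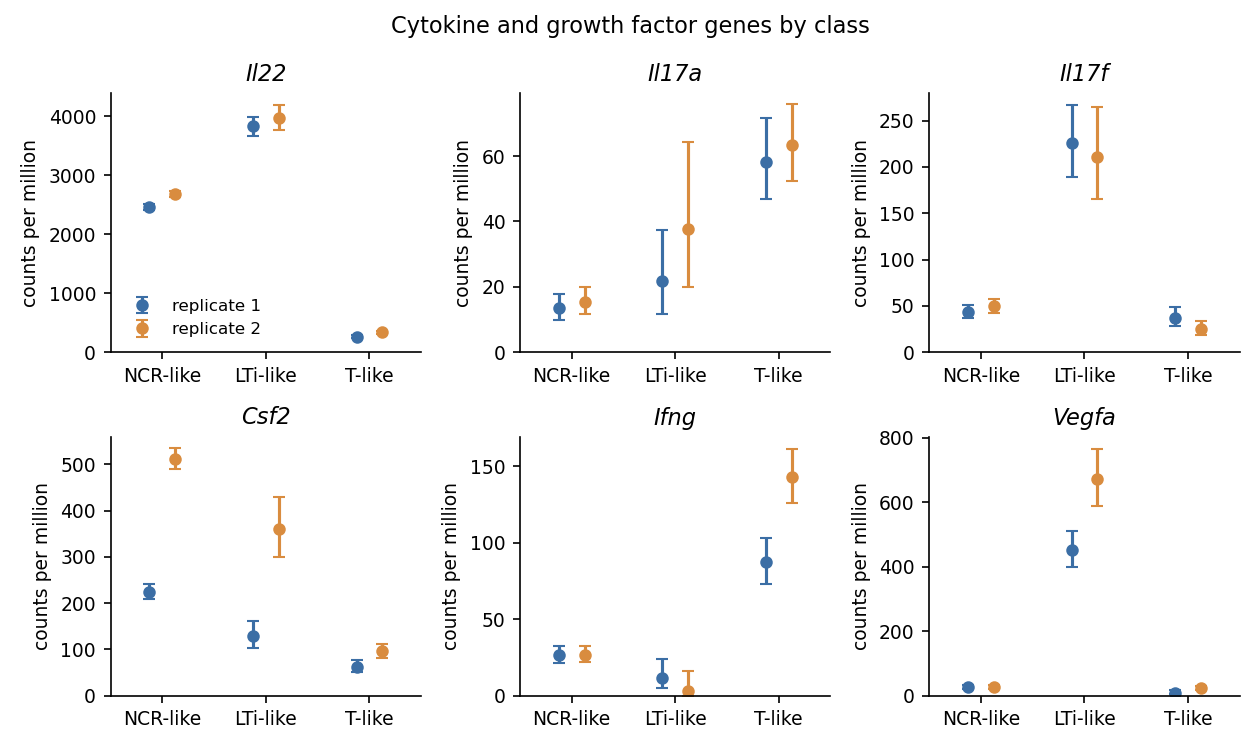
Level of 6 effector genes (CPM of the class sum, vertical axis) in NCR-like, LTi-like and T-like cells of each replicate, with exact Poisson 95% intervals for counting error. Il22, Il17f and Vegfa stood highest in LTi-like cells, and Il17a and Ifng in T-like cells.

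Antigen presentation genes separated the subsets most evenly. All 8 MHC class II genes tested were higher in LTi-like cells, with a median log2 ratio of -3.95 (camera adjusted p = 3.7e-32, adjusted p = 0.18 with an estimated correlation), and 8 also adjusted over the list alone. H2-Aa, the class II alpha chain, was 20.7-fold higher (adjusted p = 1.7e-08), Cd74, the invariant chain, 20.6-fold (adjusted p = 1.3e-07) and H2-Eb1 17.9-fold (adjusted p = 2e-06). Cd83, which stabilises class II on the cell surface, had a log2 ratio of -3.40 ± 0.15 (adjusted p = 3.5e-12). The direction was shared by both replicates but the size was not: the log2 ratio of H2-Aa was -3.23 in replicate 1 and -5.79 in replicate 2, that of Cd74 -3.01 and -5.76, and that of H2-Eb1 -2.72 and -6.49. Igkc, an immunoglobulin light chain gene of other cell types, also differed between the replicates, with a UMI in 35.2% of NCR-like cells in replicate 1 and 4.17% in replicate 2. H2-Aa in NCR-like cells was 118 CPM in replicate 1 and 23.2 CPM in replicate 2, against 1115 and 1354 CPM in LTi-like cells. With each cell thinned to equal depth, 5 of the 8 genes still passed, and without the sample block the calls of Cd74 and H2-Eb1 ended. The log2 ratios of H2-Aa, Cd74 and H2-Eb1 were -2.41, -2.57 and -2.32 with classes from Ccr6, Cd4 and Ncr1 UMIs, -3.38, -3.75 and -3.32 with those within the clusters, and -3.61, -3.61 and -3.40 with 1000 variable genes. Thinned, H2-Aa and H2-Eb1 stood at -5.16 and -4.82.

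NCR-like cells had more transcripts of cytotoxic and type 1 genes. Of 18 such genes, 10 were higher and 1, Ly6e, lower, or 12 and 1 adjusted over the list alone (median log2 ratio 1.45, camera adjusted p = 1.1e-09, adjusted p = 0.18 with an estimated correlation). Nkg7, a cytotoxic granule protein, was 15.4-fold higher (adjusted p = 7.5e-08), with log2 ratios of 4.85 and 2.63 in replicates 1 and 2. Serpinb9, an inhibitor of granzyme B, was 5.94-fold higher (adjusted p = 2.3e-09, log2 ratios 3.20 and 2.01), and Ctsw, a lymphocyte protease, 5.65-fold (adjusted p = 6.6e-07, log2 ratios 3.20 and 1.68). Ifng was 3.04-fold higher (adjusted p = 0.046) on 194 counts against 8, with log2 ratios of 1.11 and 2.85. Its call ended or turned in 11 of the alternatives tried, among them thinning to equal depth (1.25) and classes from Ccr6, Cd4 and Ncr1 UMIs (-1.14). With those UMI classes the Nkg7 call ended as well (0.12), and with 1000 variable genes its log2 ratio was 1.60, that of Serpinb9 1.14 and that of Ctsw 1.00. The Serpinb9 call ended without the sample block (2.43).

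Transcription factors parted in both directions. Of 22 tested, 9 were higher in NCR-like cells, among them Bcl11b, Prdm1, Ikzf3 and Maf, and 2 were lower, Batf3 and Tox2, or 10 and 3 adjusted over the list alone (median 0.26, camera adjusted p = 0.041, adjusted p = 0.26 with an estimated correlation). Bcl11b, a regulator of T cell and ILC2 fate, was 9.90-fold higher (adjusted p = 1.1e-06) and Maf had a log2 ratio of 1.34 ± 0.10 (adjusted p = 1.5e-08). Batf3 was 13.5-fold higher in LTi-like cells (adjusted p = 4.4e-07). Prdm1, which encodes Blimp-1, was 6.79-fold higher in NCR-like cells (adjusted p = 0.0029) on 231 counts against 4, with log2 ratios of 1.54 and 5.39. With classes from Ccr6, Cd4 and Ncr1 UMIs both turned, Bcl11b to -1.45 and Prdm1 to -0.49, and within the NCR-like and LTi-like clusters both calls ended (0.82 and 1.58). With 1000 variable genes they stood at 0.77 and 0.83, and the Prdm1 call ended, as it did without the block and with the stricter filter (1.14). Il23r, the receptor chain for IL-23, had a log2 ratio of 0.34 ± 0.15 and did not pass (adjusted p = 0.19).

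Early response genes were higher in LTi-like cells. Of 19 immediate early and heat shock genes, 15 were lower and 2, Dusp2 and Nr4a3, higher in NCR-like cells, or 16 and 2 adjusted over the list alone (median log2 ratio -0.97, camera adjusted p = 3.9e-23, adjusted p = 0.18 with an estimated correlation). Egr1 was 5.73-fold higher in LTi-like cells (adjusted p = 8e-11), and Nr4a2 and Jun had log2 ratios of -1.69 ± 0.14 (adjusted p = 4.9e-08) and -1.01 ± 0.07 (adjusted p = 6.1e-09). Levels of the heat shock genes differed far more between replicates than between classes: Hspa1a was 9.34 CPM in NCR-like and 32.0 CPM in LTi-like cells of replicate 1, and 415 and 1077 CPM in replicate 2. The Egr1 call ended without the sample block. Of 12 NF-kB pathway genes 3 were lower in NCR-like cells, Birc3, Nfkbia and Tnfaip3, and 0 higher, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.26 with an estimated correlation).

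Klf4 (GRCm38, chromosome 4, 55527143 to 55532466), a quiescence-associated factor, was 1.37-fold higher in LTi-like cells (log2 ratio -0.46 ± 0.09, adjusted p = 0.0011), at 1010 ± 285 against 728 ± 175 CPM. That call ended without the sample block, and with classes from Ccr6, Cd4 and Ncr1 UMIs the ratio was 0.09, or -0.25 and not past the threshold when those UMIs were read within the NCR-like and LTi-like clusters. Of the 18 KLF, quiescence and recirculation genes, 1 was higher in NCR-like cells, Klf3, and 5 lower, among them Tcf7 with a log2 ratio of -1.06 ± 0.12 (adjusted p = 2e-06), or 4 and 6 adjusted over the list alone (camera adjusted p = 0.048, adjusted p = 0.26 with an estimated correlation). Ccr7, the lymph node homing receptor, was 6.64-fold higher in LTi-like cells (adjusted p = 0.0063), but its log2 ratio was -0.70 in replicate 1 and -5.39 in replicate 2, and the call ended with DESeq2, without the block, with the stricter filter (-2.38) and with 1000 variable genes (-1.48).

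Gut homing and surface receptors also divided the subsets. Ccr9, the receptor for the small-intestinal chemokine CCL25, was 11-fold higher in NCR-like cells, at 396 ± 116 against 35.7 ± 13.7 CPM (adjusted p = 9.4e-11). On the log2 scale the ratio was 1.10 with 1000 variable genes, 1.76 with the stricter filter and 0.35, not past the threshold, with classes from Ccr6, Cd4 and Ncr1 UMIs. Of 11 homing genes, 7 were higher and 2, Cxcr4 and Itga4, lower in NCR-like cells, with the same counts adjusted over the list alone (camera adjusted p = 3.4e-08, adjusted p = 0.19 with an estimated correlation). LTi-like cells had more of the neuronal signal receptors Vipr2, 18.7-fold (adjusted p = 8.5e-09), and Ret, 3.98-fold (adjusted p = 1.7e-08). Of 15 environment-sensing genes these 2 were lower and 1, Ffar2, higher in NCR-like cells, or 2 and 2 adjusted over the list alone, with a median of 0.06 and a mean of -0.28 (camera lower in NCR-like cells, adjusted p = 0.041, adjusted p = 0.26 with an estimated correlation). The costimulatory ligands Tnfsf4 and Tnfsf8 were 12.8-fold and 7.87-fold higher in LTi-like cells (adjusted p = 1.8e-05 and 7e-06). Log2 ratios in replicates 1 and 2 were -2.76 and -3.93 for Tnfsf4 and -2.13 and -3.56 for Tnfsf8. Among 7 lymphotoxin and TNF ligand genes these 2 were lower and 1, Tnfsf14, higher in NCR-like cells, as they were adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.26 with an estimated correlation). Of 9 checkpoint genes 4 were higher in NCR-like cells, Icos, Tnfrsf18, Ctla4 and Cd52, and 2 lower, Pdcd1 and Tigit, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.00017, adjusted p = 0.19 with an estimated correlation). Pdcd1, the gene of PD-1, was 10.4-fold higher in LTi-like cells (adjusted p = 3.2e-05, log2 ratios -2.52 and -3.61) on 30 LTi-like counts.

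Part of the metabolic and cell cycle genes tested were higher in NCR-like cells. Of 16 glycolysis genes 7 were higher and 0 lower, among them Pfkp with a log2 ratio of 1.16 ± 0.15 (adjusted p = 2e-05), or 8 and 0 adjusted over the list alone (camera adjusted p = 0.00027, adjusted p = 0.33 with an estimated correlation). Of 19 oxidative phosphorylation genes 4 were higher and 0 lower, among them Cox5a at 0.75 ± 0.18 (adjusted p = 0.0077), or 10 and 0 adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.19 with an estimated correlation). Of 10 proliferation genes 5 were higher and 0 lower, or 6 and 0 adjusted over the list alone, with a median log2 ratio of 1.85, or 1.45 with the genes that had no LTi-like count at their bound (camera adjusted p = 0.0041, adjusted p = 0.26 with an estimated correlation). These rested on few LTi-like counts. Stmn1, a microtubule regulator of dividing cells, had 304 counts against 1, a 39.4-fold ratio with a counting interval of 7.01 to 1560, and log2 ratios of 3.58 and 5.69 in replicates 1 and 2. Mki67 had 172 against 4 (5.69-fold, adjusted p = 0.0037) and Top2a 178 against 5 (4.53-fold, adjusted p = 0.014). The Mki67 call, at a log2 ratio of 2.51, ended with each cell thinned to equal depth (2.62), with DESeq2 (2.54) and without the block (2.50), where the ratio was about as large. It also ended with classes from Ccr6, Cd4 and Ncr1 UMIs (1.08, and 0.89 within the clusters). The Top2a call, at 2.18, ended with thinning (1.27), with DESeq2 (2.22), without the block (2.24), with the UMI classes (0.34) and without cells carrying Cd3 or Trac UMIs (1.76).

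The remaining lists did not pass camera between the subsets. Of 16 interferon response genes 3 were higher in NCR-like cells, among them Irf7 and Igtp, and 1, Bst2, lower, as they were adjusted over the list alone (adjusted p = 0.20). Irf7 was 5.85-fold higher (adjusted p = 8.1e-07, log2 ratios 2.93 and 1.73) and Bst2 5.38-fold lower in NCR-like cells (adjusted p = 1.9e-07). Of 11 apoptosis regulators 1 was higher, Bcl2a1d, and 3 lower, Pmaip1, Bcl2 and Mcl1, or 3 and 3 adjusted over the list alone (adjusted p = 0.95). Pmaip1, a death-promoting BH3 protein, was 6.49-fold higher in LTi-like cells (adjusted p = 0.0024, log2 ratios -1.74 and -3.66), and its call ended without the block and with 1000 variable genes (-2.02). Of 16 senescence and DNA damage genes 1 was higher, Gadd45a, and 3 lower, Cdkn1a, Sesn1 and Cdkn1b, with the same counts adjusted over the list alone (median 0.05, mean 0.00, camera lower in NCR-like cells, adjusted p = 0.29). Cdkn1a, the cell cycle inhibitor p21, had a log2 ratio of -1.13 ± 0.11 (adjusted p = 3e-07).

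**Figure D3:**
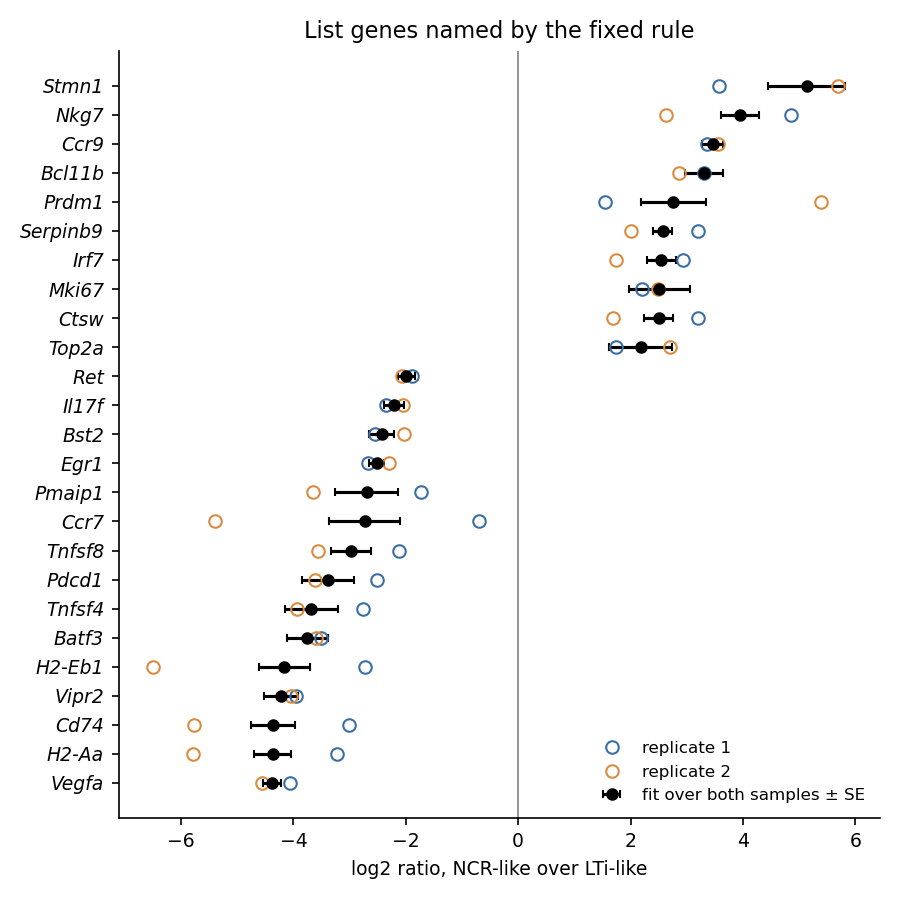
Log2 ratio of NCR-like over LTi-like cells (horizontal axis) for the 25 list genes picked by the fixed rule (vertical axis). Open circles show each replicate, and filled points show edgeR's estimate with a standard error derived from its F statistic. Vegfa, H2-Aa and Cd74 lay near -4 and Nkg7 and Ccr9 above 3, and replicates lay farthest apart for Ccr7, Prdm1 and H2-Eb1.

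In all, 854 of 7683 tested genes differed between the subsets, 491 higher and 363 lower in NCR-like cells, and 1812 had an unadjusted p under 0.05. Outside the lists, the genes farthest up in NCR-like cells were nearly absent from LTi-like cells. Ppm1j, a protein phosphatase gene, had 130 counts against 0, at least 5.61-fold higher. Grap, a signalling adaptor gene, had 94 against 0, at least 4.06-fold higher. The floor was 3 counts over both LTi-like sums. Gpr34, a lysophosphatidylserine receptor gene, had 282 counts against 1 (36.5-fold, counting interval 6.50 to 1447), Zdhhc2 109 against 1 (14.1-fold, 2.48 to 562) and Acsbg1 162 against 2 (10.5-fold, 2.86 to 87.3). These intervals cover counting error only, and the log2 ratios in replicates 1 and 2 were 4.80 and 1.33 for Acsbg1, 4.76 and 3.67 for Gpr34 and 2.96 and 3.48 for Zdhhc2. The calls of these 5 genes ended without the block. With classes from Ccr6, Cd4 and Ncr1 UMIs the log2 ratios of Grap and Zdhhc2 turned to -0.73 and -1.53 and the calls of Ppm1j (0.73), Gpr34 (0.43) and Acsbg1 (0.44) ended, that of Gpr34 also within the clusters (1.98). The Zdhhc2 and Acsbg1 calls also ended with DESeq2 and with the stricter filter (2.06 and 1.36), and the Grap call with the looser filter (2.07). With 1000 variable genes the Grap (1.18) and Zdhhc2 (1.10) calls ended, and Ppm1j, Gpr34 and Acsbg1 stood at 1.65, 1.38 and 1.95. The genes farthest up in LTi-like cells were Ppfibp2, 27.5-fold (adjusted p = 8e-07), the kinase gene Pak1, 10.5-fold (adjusted p = 2.4e-05), and the interferon gamma receptor chain Ifngr2, 7.76-fold (adjusted p = 3.6e-06). They were followed by BC018473, 7.51-fold (adjusted p = 0.00015), and the complement factor gene Cfp, 7.26-fold (adjusted p = 0.00042). Each of the 5 had 12 to 49 counts in NCR-like cells. Log2 ratios in replicates 1 and 2 were -3.98 and -4.53 for Ppfibp2 and -2.63 and -3.28 for Pak1. The Cfp call ended without cells that carried a B, plasma or myeloid marker UMI (-1.76), and the Pak1 and Cfp calls ended without the block.

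The size of the contrast depended on how cells were put into classes. Of the 39 genes named by the fixed rule that passed, 26 moved by over 1.5 times with 1000 variable genes, all toward 0, and 8 lost their call. With classes from Ccr6, Cd4 and Ncr1 UMIs 27 of the 34 with a value moved that far, 25 of them to a smaller size, 7 lost their call and 6 turned. With 1000 variable genes Vegfa stood at -3.66, Il17f at -1.36, Irf7 at 1.07, Bst2 at -1.56 and Stmn1 at 2.40, and with the UMI classes Vegfa at -3.23, Egr1 at -1.13, Irf7 at 1.24, Bst2 at -1.38 and Stmn1 at 1.75. With the stricter cell filter 17 moved, all toward 0, and 5 lost it. Without the sample block 20 lost their call and 0 moved that far. Leaving out replicate 1 moved 14 of them and leaving out replicate 2 moved 19 by over 1.5 times. Ratios of single replicates were not edgeR's estimates and used a prior count. For genes with few counts, part of the move may thus come from the change of estimate. While 0 changed sign, the rule had fixed this in advance for all but the always-given genes. Of the 18 lists, 7 turned and 4 lost their call with classes from Ccr6, Cd4 and Ncr1 UMIs, among them checkpoint and homing genes, which turned, and immediate early genes, which lost it. The lists were not retested with 1000 variable genes, thinned cells or Scrublet calls removed, so whether their calls hold there is not known. Nor were they retested with DESeq2, no filter on low counts or only the compared classes. The transcription factor call ended with the stricter filter and without the block, the KLF call with the stricter filter, at resolution 0.3 and without the cluster led by heat shock genes, and the environment-sensing call at resolutions 0.3 and 1.0 and without that cluster. The TNF ligand call ended without cells carrying B, plasma or myeloid marker UMIs, and the checkpoint call without the block. With fry, a rotation test that compares a list with no other genes, 13 of the 14 lists that passed with camera lost their call and oxidative phosphorylation alone kept it.

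The second comparison asked how the T-like cells differed from the NCR-like cells. T-like cells had little Il22, at 299 ± 53.2 CPM or 8.31-fold less than NCR-like cells (adjusted p = 8.3e-17), and 4.34-fold less Csf2 (adjusted p = 3.6e-09). They had 4.36-fold more Il17a (60.8 ± 3.58 against 14.4 ± 1.37 CPM, adjusted p = 1.5e-07) and 4.45-fold more Ifng (115 ± 39.4 against 26.7 ± 0.180 CPM, adjusted p = 3.5e-08). Cd40lg (chromosome X, 57212143 to 57224042), the CD40 ligand of helper T cells, was 42.1-fold higher (adjusted p = 1.9e-15) and Ccr2, a chemokine receptor, 19.8-fold (adjusted p = 3.3e-14). Fcer1g, an adaptor of activating receptors in innate cells, was 26.4-fold lower (adjusted p = 5.1e-17). In all 1134 genes differed, 558 higher and 576 lower in T-like cells. The Csf2 call ended without the sample block.

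Of 11 cytokine genes 1, Il17a, was higher and 6 lower in T-like cells, or 1 and 9 adjusted over the list alone (camera adjusted p = 9.6e-09, adjusted p = 0.46 with an estimated correlation). Of 9 checkpoint genes 5 were higher, Tigit, Pdcd1, Ctla4, Cd52 and Icos, and 2 lower, Lag3 and Tnfrsf9, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.0084, adjusted p = 0.46 with an estimated correlation). Ctla4 was 3.66-fold higher, at 539 ± 1.65 against 153 CPM (adjusted p = 1.5e-10), Pdcd1 5.32-fold (adjusted p = 0.00017, log2 ratios 1.73 and 2.48) and Tnfrsf9 2.16-fold lower (adjusted p = 0.015, log2 ratios -1.83 and -0.65, lost with DESeq2 and without the block). Of 22 transcription factors 7 were higher and 2, Tox and Id2, lower, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.040, adjusted p = 0.46 with an estimated correlation). Bcl11b was 4.09-fold higher (adjusted p = 1.5e-10), Zbtb16, which encodes PLZF, 2.38-fold higher (adjusted p = 4.6e-07) and Tox 2.37-fold lower (adjusted p = 8.7e-05), and the Zbtb16 and Tox calls ended without the block. Of 18 type 1 and cytotoxic genes 3, Ifng, Fasl and Nkg7, were higher and 7 lower, or 4 and 8 adjusted over the list alone (camera lower, adjusted p = 0.014, adjusted p = 0.46 with an estimated correlation), with Gzmc 4.71-fold lower (adjusted p = 9e-06). Among 7 TNF ligand genes Cd40lg was higher and Tnfsf4 and Tnfsf11 were lower, as they were adjusted over the list alone. The list's median of -0.31 and mean of -0.26 went against its test, which gave a higher level (adjusted p = 0.043, adjusted p = 0.65 with an estimated correlation). Tnfsf11, the gene of RANKL, was 2.16-fold lower (adjusted p = 3.9e-07). Tnfsf4 had 0 counts in T-like against 23 in NCR-like cells, at least 3.58-fold lower. Neither call held without the block. Without it, the list calls of TNF ligands, type 1 genes, transcription factors and checkpoint genes also ended. With fry, the calls of cytokines, TNF ligands and type 1 genes ended.

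Gut homing genes went both ways in T-like against NCR-like cells, with 3 of 11 higher and 5 lower, or 4 and 5 adjusted over the list alone (adjusted p = 0.50), among them Itga4, an integrin subunit, 6.58-fold lower (adjusted p = 2e-10), and Ccr9, 5.37-fold lower (adjusted p = 2.8e-11). Ret was 5.14-fold higher (adjusted p = 3.3e-11) and the clock gene Dbp 2.61-fold lower (adjusted p = 0.017, lost with DESeq2 and without the block), in an environment-sensing list with 3 of 15 higher and 5 lower, or 3 and 6 adjusted over the list alone. That list's median of -0.12 and mean of -0.08 went against its test for a higher level (adjusted p = 0.87). Bcl2a1b, a survival gene, was 4.05-fold higher (adjusted p = 2e-09) and Pmaip1 3.03-fold higher (adjusted p = 0.028, log2 ratios 0.44 and 2.63, lost with DESeq2 and without the block), in an apoptosis list with 3 of 11 higher and 1 lower, or 3 and 2 adjusted over the list alone (adjusted p = 0.28). Cd83 was 5.23-fold lower (adjusted p = 1.3e-07, log2 ratios -1.79 and -2.81) in an MHC class II list with 1 of 8 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.12). Tpi1 was 2.46-fold lower (adjusted p = 2.5e-05) among 16 glycolysis genes with 1 higher and 2 lower, or 3 and 2 adjusted over the list alone. The median of that list was 0.11 and its mean -0.03, and its test was for a lower level (adjusted p = 0.94). Gadd45g was 2.45-fold lower (adjusted p = 4.7e-05) among 16 senescence genes with 4 higher and 2 lower in either count, a median of -0.01, a mean of 0.01 and a test for a higher level (adjusted p = 0.94). Il17f (log2 ratio -0.54 ± 0.19, adjusted p = 0.068), Il23r (-0.19 ± 0.12, adjusted p = 0.37) and Klf4 (0.10 ± 0.08, adjusted p = 0.53) did not pass. Il17f passed with no filter on low counts (-0.58) and with only these classes in the fit (-0.55). The KLF list had 4 of 18 higher and 2 lower in either count (adjusted p = 0.78), and immediate early genes had 2 of 19 higher and 6 lower, or 2 and 9 adjusted over the list alone (adjusted p = 0.28). NF-kB genes had 1 of 12 higher and 4 lower, or 1 and 5 adjusted over the list alone (adjusted p = 0.23), and oxidative phosphorylation 3 of 19 higher and 1 lower, or 4 and 1 (adjusted p = 0.39). Interferon genes had 0 of 16 higher and 1 lower in either count (adjusted p = 0.91). Proliferation genes had 0 of 10 higher and 1 lower in either count, with a median of 0.08 and a mean of -0.02 and a test for a lower level (adjusted p = 0.87).

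The third comparison set T-like against LTi-like cells, and 1507 genes differed, 814 higher and 693 lower in T-like cells. Il22 was 12.5-fold lower in T-like cells (adjusted p = 9.8e-18), Il17f 6.77-fold (adjusted p = 3.3e-09), Vegfa 31.9-fold (adjusted p = 2.8e-13) and Csf2 2.78-fold (adjusted p = 4.9e-06). Ifng was 13.5-fold higher (adjusted p = 6e-07, log2 ratios 2.85 and 5.26) and Il17a 2.24-fold higher (adjusted p = 0.0063). Icos, the inducible costimulator of T cells, was 5.92-fold higher (adjusted p = 2.9e-15) and Ctla4 9.25-fold (adjusted p = 1.3e-11). Cd83 was 55.2-fold lower (adjusted p = 2.5e-14) and H2-Aa 34.8-fold lower (adjusted p = 3.4e-09, log2 ratios -4.18 and -6.04). The Csf2 and Il17a calls ended without the sample block, and the Il17a call also with DESeq2.

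Large T-like to LTi-like contrasts lay in several of the lists. Higher in T-like cells were Cd40lg, 62.7-fold on 6 LTi-like counts (adjusted p = 4.9e-12, log2 ratios 6.21 and 5.10), Bcl11b, 40.5-fold on 7 (adjusted p = 2.4e-11), and Nkg7, 27.5-fold (adjusted p = 6.3e-10, log2 ratios 5.57 and 3.59). So were Ccr2, 26.2-fold (log2 ratios 5.29 and 4.04), Fasl, 15.5-fold (log2 ratios 3.91 and 3.35), and Dusp2, 7.41-fold (log2 ratios 2.46 and 3.82). Mki67 was 6.21-fold higher on 4 LTi-like counts. Stmn1 had 129 counts against 1, a 35.8-fold ratio with a counting interval of 6.31 to 1425 (log2 ratios 3.70 and 5.46). Lower in T-like cells were Batf3, 44.0-fold on 5 T-like counts (log2 ratios -4.49 and -5.54), Ccr7, 33.0-fold on 7 (log2 ratios -4.35 and -4.90), Vipr2, 32.7-fold, and H2-Eb1, 29.8-fold (log2 ratios -3.56 and -6.79). So were Fcer1g, 23.3-fold, Tox2, 12.8-fold (log2 ratios -3.07 and -4.10), Itga4, 11.1-fold, Lif, 10.8-fold (log2 ratios -2.17 and -3.97), Tnfsf8, 10.2-fold (log2 ratios -2.37 and -3.95), and Egr1, 7.78-fold. Each passed at an adjusted p of 0.0017 or less, and the Ccr7 and H2-Eb1 calls ended without the block. Tnfsf4 had 0 counts in T-like against 38 in LTi-like cells, at least 45.6-fold lower. Klf4 was 1.29-fold lower (adjusted p = 0.0047), a call lost with DESeq2, with no filter on low counts and without the block. Il23r (log2 ratio 0.15 ± 0.16, adjusted p = 0.59) did not pass.

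By list, T-like cells were lower than LTi-like cells in effector cytokines, with 1 of 11 higher and 6 lower, or 2 and 6 adjusted over the list alone (camera adjusted p = 1.9e-18, adjusted p = 0.20 with an estimated correlation). Immediate early genes had 1 of 19 higher and 14 lower, the same counts adjusted over the list alone (adjusted p = 1.9e-18, adjusted p = 0.20 with an estimated correlation). MHC class II genes had 0 of 8 higher and 7 lower, or 0 and 8 adjusted over the list alone (adjusted p = 1.3e-22, adjusted p = 0.17 with an estimated correlation). NF-kB genes had 0 of 12 higher and 7 lower, or 0 and 10 adjusted over the list alone (adjusted p = 0.00032, adjusted p = 0.29 with an estimated correlation). T-like cells were higher in checkpoint genes, with 4 of 9 higher and 1 lower, or 5 and 3 adjusted over the list alone (adjusted p = 2.1e-07, adjusted p = 0.20 with an estimated correlation). Homing genes had 7 of 11 higher and 2 lower, as they had adjusted over the list alone (adjusted p = 0.0020, adjusted p = 0.20 with an estimated correlation), a call that ended without the sample block. Oxidative phosphorylation had 10 of 19 higher and 1 lower, with the same counts adjusted over the list alone (adjusted p = 0.0015, adjusted p = 0.20 with an estimated correlation). Transcription factors had 9 of 22 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.0043, adjusted p = 0.20 with an estimated correlation), and glycolysis 7 of 16 higher and 1 lower, or 9 and 1 adjusted over the list alone (adjusted p = 0.0073, adjusted p = 0.44 with an estimated correlation). The NF-kB and glycolysis calls ended with fry.

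Other lists did not pass between T-like and LTi-like cells. TNF ligands had 2 of 7 higher and 3 lower, or 2 and 4 adjusted over the list alone (adjusted p = 0.51). Type 1 and cytotoxic genes had 8 of 18 higher and 3 lower in either count (adjusted p = 0.13) and proliferation 4 of 10 higher and 1 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.064), and both passed without the sample block. The KLF list had 4 of 18 higher and 5 lower, or 7 and 7 adjusted over the list alone (adjusted p = 0.38), apoptosis 2 of 11 higher and 2 lower, or 3 and 2 (adjusted p = 0.47), and interferon 4 of 16 higher and 2 lower in either count (adjusted p = 0.30). Environment sensing had 1 of 15 higher and 2 lower in either count (adjusted p = 0.30) and passed with fry. Senescence genes had 3 of 16 higher and 4 lower in either count, with a median of 0.09 and a mean of 0.01 against a test for a lower level (adjusted p = 0.51).

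Cxxc1 lies on chromosome 18 at 74216124 to 74221496 (GRCm38) and was detected at a like level in the ILC3 classes. Its level was 68.3 ± 7.46 CPM in NCR-like, 82.9 ± 11.1 in LTi-like and 74.5 ± 7.52 in T-like cells (mean ± SD, n = 2). None of the class ratios passed, with log2 ratios of -0.28 ± 0.19 for NCR-like over LTi-like (adjusted p = 0.42, 95% interval -0.65 to 0.09), 0.18 ± 0.14 for T-like over NCR-like (adjusted p = 0.46) and -0.09 ± 0.20 for T-like over LTi-like (adjusted p = 0.79). LTi-like cells gave 54 and 26 Cxxc1 UMIs in replicates 1 and 2, or 90.8 CPM (exact Poisson 95% interval 68.2 to 119) and 75.1 CPM (49.0 to 110). Of the 17 H3K4 methyltransferase complex genes tested, 1 differed between NCR-like and LTi-like cells, also adjusted over the list alone (camera adjusted p = 0.29). That gene, Kmt2a, a methyltransferase of the MLL family outside the SETD1 complexes, was lower in NCR-like cells at 224 ± 18.9 against 370 ± 11.7 CPM (log2 ratio -0.70 ± 0.14, adjusted p = 0.0017). Kmt2a was also lower in T-like than in LTi-like cells (log2 ratio -0.79 ± 0.14, adjusted p = 0.00036), the only member of 17 to differ there, also adjusted over the list alone (median -0.12, mean 0.07, camera lower, adjusted p = 0.76). Kmt2d alone was higher in T-like than in NCR-like cells (0.44 ± 0.12, adjusted p = 0.016, 1 of 17 also adjusted over the list alone, with a camera adjusted p of 0.72). Setd1a, which encodes the catalytic partner of CXXC1, stood at 32.7 ± 2.45 CPM in NCR-like and 51.6 ± 8.72 in LTi-like cells and did not pass (log2 ratio -0.61 ± 0.26, adjusted p = 0.15).

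**Figure D4:**
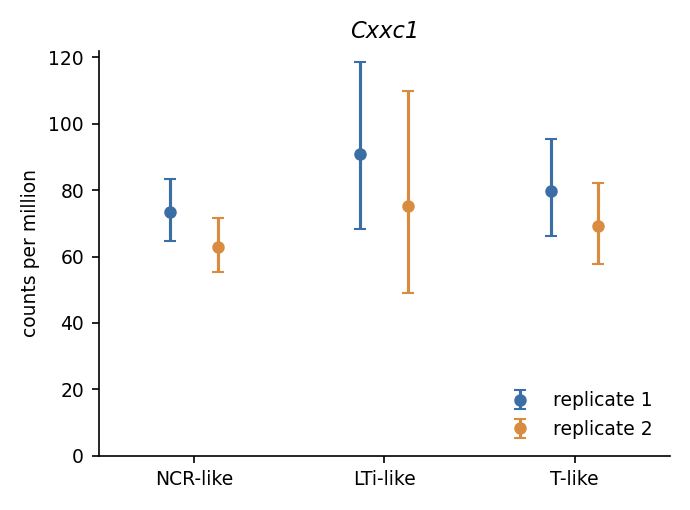
Level of Cxxc1 (CPM of the class sum, vertical axis) in NCR-like, LTi-like and T-like cells (horizontal axis) of replicates 1 and 2, with exact Poisson 95% intervals for counting error. The NCR-like, LTi-like and T-like values ran from 63.0 to 90.8 CPM, with overlapping intervals.

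Shares of cells with a UMI were compared after thinning every cell to 1300 UMIs. An Il22 UMI was found in 66.3% ± 2.25 of LTi-like, 53.5% ± 0.964 of NCR-like and 17.7% ± 1.38 of T-like cells (SD, n = 2; unthinned 63.9%, 57.8% and 22.5%). An Il22 UMI was also found in 17.2% and 4.76% of stromal-like cells in replicates 1 and 2 (16 of 93 and 1 of 21 cells), and whether through free RNA, doublets or a mixed cluster was not tested. The T-like share in replicate 1, 18.7%, lay near that level. An Il17f UMI was found in 14.9% ± 5.27 of LTi-like cells (unthinned 13.6%), 2.31% of NCR-like (3.43%) and 1.45% of T-like cells (2.36%), against 0 of 93 and 0 of 21 stromal-like cells in replicates 1 and 2, which allow shares of up to 3.89% and 16.1% (exact Clopper-Pearson 95% bounds). For Il17a the shares were 4.84% ± 1.8 of T-like (unthinned 4.94%), 2.90% of LTi-like (3.08%) and 0.907% of NCR-like cells (1.46%), against 2 of 93 and 0 of 21 stromal-like cells, too few to set a background. For Ifng they were 9.92% ± 3.95 of T-like (unthinned 12.4%), 2.55% ± 0.173 of NCR-like (3.34%) and 1.04% ± 1.47 of LTi-like cells (1.14%), against 3 of 93 and 2 of 21 stromal-like cells (mean 6.37%), again too few to set a background. Csf2 UMIs were found in 24.0% ± 9.72 of NCR-like (unthinned 28.7%), 16.3% ± 6.56 of LTi-like (14.3%) and 7.40% ± 3.54 of T-like cells (9.29%). Among stromal-like cells 4 of 93 and 3 of 21 had one (mean 9.29%), again too few to set a background. Klf4 was found in 49.2% ± 8.31 of NCR-like, 60.5% ± 10.7 of LTi-like and 48.7% ± 6.65 of T-like cells (unthinned 56.6%, 57.7% and 54.9%) and in 51.2% of stromal-like cells, a type that can express it. Cxxc1 was found in 8.14% ± 1.69 of NCR-like, 8.75% ± 2.88 of LTi-like and 9.10% ± 0.768 of T-like cells (unthinned 11.4%, 10.9% and 12.1%), and in 10.7% of stromal-like cells. Median depth before thinning was 3274 and 1886 UMIs in stromal-like, 1899.5 and 1705 in NCR-like, 1461 and 1363 in LTi-like and 1907 and 1671 in T-like cells. Shallower cells left out numbered 229 and 449 NCR-like, 134 and 105 LTi-like, 101 and 272 T-like and 42 and 16 stromal-like in replicates 1 and 2.

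Stromal and heat shock genes led the differences between the whole-sample profiles of the replicates. Across 17946 genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.970 and Spearman's rho 0.941. Of 1896 genes at 100 CPM or more in either replicate, 102 differed by over 2-fold, as did 72 of 1890 in the ILC3 classes alone. Replicate 1 was higher in the collagen genes Col1a1 (1079 against 17.3 CPM, 62.3-fold), Col1a2 (59.7-fold) and Col3a1 (59.3-fold) and in Sparc, a matrix protein gene (56.0-fold). Col1a1 was higher in every class of replicate 1, among them stromal-like (12011 against 751 CPM), NCR-like (93.4 against 6.25) and T-like cells (90.3 against 3.76). The share of stromal-like cells alone thus does not account for its fold, and the cause was not tested. Also higher in replicate 1 was the immunoglobulin light chain gene Iglc3 (42.8-fold). Of the 1116 Iglc3 UMIs in NCR-like cells of replicate 1, 1105 came from 1 cell. Replicate 2 was higher in the heat shock genes Hspa1b (512 against 36.2 CPM, 14.1-fold), Hspa1a (10.3-fold) and Hsph1 (7.85-fold), in the chemokine gene Cxcl3 (5.87-fold) and in Cables1 (5.02-fold).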

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

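The cell filters, resolutions, scaling, tests and UMI classes tried were chosen before the data were examined. UMI classes within the NCR-like and LTi-like clusters and the fits without the cluster led by heat shock genes, without cells with Cd3 or Trac UMIs and without cells with B, plasma or myeloid marker UMIs were chosen only after the result was seen. Of 697 alternative values for the 42 named genes of NCR-like against LTi-like cells, 620 kept their direction and side of the threshold, 66 lost the call, 4 gained it and 7 reversed. The T-like comparisons had only 5 alternatives with a test for each gene, in scaling, test, low-count filter, block and classes fitted, and none in cell filter, clustering, thinning or UMI classes. There 131 of 144 kept both against NCR-like cells and 152 of 160 against LTi-like cells, with 0 reversed. With 1 sample left no test and no count of genes is possible, so leaving out a replicate gives values only. Reversals there were counted only for named genes past the threshold, and 0 were found. The rule asked all but the always-given genes for the same direction in both samples. That 0 was thus largely fixed in advance and is no sign of robustness. The share of each class, the Cxxc1 levels and the thinned shares without 1 replicate are the other replicate's values, of which the report gives part singly and the rest as a mean with its SD. LTi-like depth, with 594534 and 346372 UMIs, limits genes with few counts. Except where the construction is given, the cause was not tested.

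The number of genes that differ between NCR-like and LTi-like cells, 854, became 1061 with no filter on low counts (786 higher and 275 lower), 995 at resolution 0.3, 380 with DESeq2, 443 with the stricter cell filter, 443 with 1000 variable genes, 511 with classes from Ccr6, Cd4 and Ncr1 UMIs (5930 genes tested) and 262 with those within the clusters (5180 tested), where fewer genes and cells were tested. DESeq2 gave 420 for T-like against NCR-like and 865 for T-like against LTi-like cells. With no replicate block, which leaves the difference between the samples in the spread, the counts were 68, 147 and 376, and 1 list passed for T-like against NCR-like cells. Shared with the main NCR-like against LTi-like calls in the same direction were 380 of DESeq2's genes, 68 without the block, 396 with the stricter filter, 337 with 1000 variable genes, 239 with the UMI classes and 234 with those within the clusters. The number of lists past the threshold was 14, 5 and 9 at the preset correlation and 0 in all 3 comparisons by camera with an estimated correlation. Camera with an estimated correlation also missed a shifted list in simulated data. Genes there were drawn independently, so that miss does not discount its result for lists whose genes move together. Fry gave 1 list for NCR-like against LTi-like and 2 for T-like against NCR-like cells. Classes from UMIs gave 7.

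The mean share of NCR-like cells was 58.3% at resolution 0.3, 33.8% with 1000 variable genes and 56.8% with Scrublet calls removed. Since that removed 1 cell per sample, its shifts show how far reclustering alone moves the classes. LTi-like cells were 12.7% with the stricter filter and 15.4% with 1000 variable genes. Unnamed cells were 13.1% and 6.39% with the looser and stricter filters, 5.79% and 12.3% at resolutions 0.3 and 1.0, 22.2% with 1000 variable genes and 5.63% with Scrublet calls removed.

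With classes from Ccr6, Cd4 and Ncr1 UMIs the NCR-like over LTi-like log2 ratios reversed for Ifng (-1.14), Klf4 (0.091), Bcl11b (-1.45), Prdm1 (-0.49), Grap (-0.73) and Zdhhc2 (-1.53). By construction that class took in other cells, since 125 of its 259 LTi-like cells in replicate 1 and 92 of 161 in replicate 2 lay outside the NCR-like and LTi-like clusters. Within those clusters Ifng was -0.038.

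Lists that reversed for NCR-like against LTi-like cells with the UMI classes were ILC_transcription_factors (adjusted p = 0.838), NFkB_activation (0.20), apoptosis_regulators (0.0371), interferon_response (0.0718), homing_retention (0.838), environment_sensing (0.139) and checkpoint_costimulation (4.39e-05). Within the clusters they were senescence_DNA_damage (0.834), apoptosis_regulators (0.898), interferon_response (0.0803) and environment_sensing (0.834). The apoptosis_regulators list, at 0.95 as reported, reversed with the looser filter (0.793), at resolution 0.3 (0.959) and without cells with Cd3 or Trac UMIs (0.750). Over their 13 alternatives each, adjusted p ran from 0.0248 to 0.838 for ILC_transcription_factors, 0.00062 to 0.264 for NFkB_activation, 0.0371 to 0.984 for apoptosis_regulators, 0.0689 to 0.335 for interferon_response, 1.06e-09 to 0.838 for homing_retention, 0.0188 to 0.834 for environment_sensing, 2.07e-05 to 0.205 for checkpoint_costimulation and 0.0738 to 0.834 for senescence_DNA_damage.

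Without thinning, the shares of cells with a UMI were 11.4% of NCR-like and 12.1% of T-like cells for Cxxc1, 57.8%, 63.9% and 22.5% of NCR-like, LTi-like and T-like cells for Il22, 1.46% of NCR-like cells for Il17a, 3.43% of NCR-like and 2.36% of T-like cells for Il17f and 3.34% of NCR-like cells for Ifng (thinning also leaves out shallow cells). Pearson's r between the samples was 0.976 with log2(CPM + 10) and 0.981 in the ILC3 classes alone, where Spearman's rho was 0.952.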

Other observations

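The tests on doublets, on free RNA of T cells, and on the MHC class II genes still tested at equal depth were chosen only after the result was seen, as were the genes of the unnamed class described here.

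The unnamed cluster held cells with transcripts of cytotoxic lymphocytes and of T cells. Its highest marker scores were 1.28 for the T cell list, 0.83 for the NK and ILC1 list and 0.75 for the NCR list. The T-like cluster scored 0.55 for the T cell list but 1.00 for a separate gamma delta T cell list. On that list the unnamed cluster scored 0.16. An ILC3 score of -0.73 kept the unnamed cluster out of the ILC3 classes. At resolution 1.0 the unnamed cells included a cluster of 404 with a T cell score of 1.84 and an NCR score of -0.74, and another of 346 with scores of -0.94 and 1.32, so the pooled levels below may mix unlike cells. At equal depth a UMI of a T cell receptor variable segment was found in 14.6% and 11.2% of its cells in replicates 1 and 2, against 14.7% and 13.9% of T-like cells. Gzmb, the granzyme B gene, stood at 770 ± 18.1 CPM (SD, n = 2) there against 29.2 ± 4.50 in NCR-like and 22.2 CPM in T-like cells, and Nkg7, a cytotoxic granule gene, at 609 ± 99.9 against 143 ± 45.6 CPM in NCR-like cells. Ifng was 183 ± 37.1 CPM against 115 ± 39.4 in T-like cells, and Ccl4, a chemokine gene, 263 ± 113 against 45.5 ± 38 CPM in NCR-like cells. Gzma, Ccl5 and Il21r also led the cluster and took part in its naming or clustering, so their levels are no separate finding. Il22 stood at 786 ± 190 CPM. A Cd4 UMI was found in 26.2% and 20.9% of the unnamed cells of replicates 1 and 2, and a Cd8a UMI in 27.3% and 4.72%, and both genes took part in the clustering. These are levels without a test, and the share of the class ran from 5.63% to 22.2% over the alternatives.

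Trac, Trdc and variable segments of both T cell lineages were more frequent in T-like than in NCR-like cells. At equal depth gamma or delta segments were found in 10.8% and 9.41% of T-like cells and 10.9% and 8.04% of unnamed cells, against 1.65% and 2.37% of NCR-like cells, and alpha or beta segments in 4.26% and 3.15% of unnamed cells. Stromal-like cells had gamma or delta segments in 0.0% of 93 and 9.52% of 21 cells in replicates 1 and 2, too few cells to set a background. Of these genes Trac, Trdc and Trdv4 took part in the clustering. A UMI of Trac, the alpha chain constant gene, without Trdc was found in 59.4% and 55.2% of T-like cells of replicates 1 and 2, and Trdc, the delta chain constant gene, without Trac in 12.3% and 9.54%. Both were found in 3.10% and 3.94%, and neither in 25.3% and 31.3%. In NCR-like cells Trac alone was found in 7.83% and 5.15% and Trdc alone in 3.91% and 4.50%. The most frequent variable segments were Trgv2, in 7.48% and 7.61% of T-like cells, and Trdv4, in 6.84% and 4.22%, against 0.474% and 0.375% and 1.60% and 2.58% of NCR-like cells. Not all receptor constant genes went this way. On average over the replicates, Trbc1 was found in 30.5% of T-like cells against 53.4% and 45.3% of NCR-like clusters 1 and 2. For Tcrg-C4 the shares were 12.8% against 26.0% and 28.5%. Trbc2, Tcrg-C1 and Tcrg-C2 were more frequent in T-like cells.

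T cell receptor genes in cells sorted as ILC3s were the first pattern weighed, and the design gives no group for a biological explanation, so none was tested. At equal depth, a UMI of any of 93 T cell receptor variable segments was 7.926 and 5.464 times as frequent in T-like as in NCR-like cells of replicates 1 and 2. Alpha or beta segments, none of which was used for clustering, were found in 3.86% and 5.01% against 0.275% and 0.178%, so T cells may have passed the sort. Doublets of a T cell and an ILC3 would hold more UMIs, but the median per cell was at most 1.004 times that of NCR-like cells (0.9801 in the other replicate). Free RNA would reach all classes alike, but a Cd3e UMI was at least 28.76 times as frequent in T-like cells (30.54 in the other replicate); Cd3e helped to form the clusters, while Cd3d, which did not, was found in 30.0% and 18.7% of T-like against 1.24% and 0.652% of NCR-like cells. The gate of the sort is not given in the labels, so which cells it should have removed stays open.

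MHC class II genes in LTi-like cells were the second pattern, and no biological explanation was tested. A UMI of any listed B, plasma or myeloid marker except Igkc, Jchain and Cst3 was found in 10.7% and 7.53% of LTi-like cells, and in 7.89% and 3.56% of NCR-like cells, so many of these need not be such cells. As far as these markers find them, B or myeloid cells did not account for the pattern, since without marked cells the median log2 ratio of the 8 genes was -4.027, or 1.019 times that with all cells. At equal depth 5 of the 8 genes passed, a share of 0.625, because H2-Oa and H2-DMb2 no longer passed the filter on low counts and H2-DMa went from -1.77 ± 0.44 to -1.13 ± 0.83, so for these 3 genes a depth effect cannot be told apart from a class difference. Over the 6 genes still tested at equal depth, H2-DMa among them, the median was -4.534, or 1.147 times that with all UMIs. The ratios are of class sums scaled to the same total. Apart from the shallow cells it leaves out, thinning keeps the expected proportions, so this value could hardly have shrunk and decides nothing about depth.

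Higher immediate early genes in LTi-like cells were the third pattern, again with no biological explanation tested. The difference was not carried by 1 library, as the list's median log2 ratio of LTi-like over NCR-like cells was 0.7422 in 1 replicate and 0.9354 in the other. Without the NCR-like cluster led by heat shock genes 17 of the 17 members past the threshold still passed in the same direction, a share of 1, but that cluster held more heat shock transcripts, so leaving it out widens their difference and the test decides nothing about it. Cell handling that acts differently on the classes may contribute and was not tested; with classes from Ccr6, Cd4 and Ncr1 UMIs the immediate early list no longer passed (adjusted p = 0.232, the highest of its 13 alternatives, which began at 7.49e-44).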
